A study of Mus musculus with 2 samples.

How the data were processed

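Total RNA of 2 neural progenitor lines, overexpressing EGFP or Pax6, was measured 24 h after doxycycline on 1 Agilent 1-colour whole mouse genome array each. RNA was extracted with ISOGEN and labelled with Cy3 after linear amplification, per the labels' protocols. The authors scanned the arrays and extracted spots with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited intensity values are the software's processed signals, background-subtracted and detrended within each array, per the file headers, and not normalized between arrays. The deposited series table holds the same intensity values on a linear scale, not centred, with a largest relative difference of 0.0 from the scanner files, so it gave no independent alternative. The deposited flags (unit other) mark spots that are well above background, saturated or outliers, per the file headers. Spots were well above background when they exceeded it by 13.0 of its SDs, per the file headers. The 2 arrays lay on 1 slide and were scanned together, so slide and scan do not separate the groups.

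Each array held 45018 spots, of which 43379 were non-control spots of 41174 probes. Outlier spots numbered 51 on the EGFP array and 52 on the Pax6 array and were left out, which kept 43283 spots and 41168 probes on both arrays. The processed signal was put on the log2 scale and the array's 75th percentile of it was subtracted (a signal of 854 on the EGFP array and 991 on the Pax6 array). Replicate spots were averaged, a gene took its probe with the highest mean over both arrays, and differences are Pax6 minus EGFP. A gene was used when it was well above background on at least 1 array, which left 19251 genes, 17832 of them measured on both arrays. For the other 1419 genes the difference is a lower bound, written as "at least", of the brighter array's value against the higher of the dim probe's own value and the lowest signal well above background (10.4 on the EGFP array, 9.30 on the Pax6 array). Bounds also enter medians and counts of gene lists. Probe accessions matched current mouse gene symbols for 22951 of 41168 probes (55.7%), and the array's own, older names were kept for the other 18217. Coordinates are those of the array design, on mouse build mm7. No annotation of that build was used here, so exons and untranslated regions are not stated.

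With 1 array per group no test across arrays was made and no p-value is given. Genes were counted by a fixed rule of size, at least 2-fold, and "higher" and "lower" describe these arrays. Gene lists are described by the median difference of their measured genes, its 95% bootstrap interval over genes (2000 draws, covering the choice of genes only), and its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. The measurement error given after ± is the software's error of the signal, with a multiplicative part of 10.0%, carried to the log2 difference. It had a median of 0.20. The 170 probes with replicate spots had a median SD of 0.08 on the EGFP array, 0.07 on the Pax6 array and 0.08 for the difference, below the median error. The SD of the difference was larger for some probes, with a 95th percentile of 0.391, so for these the error given is too small. Of 1642 replicate spots, 9 lay at least 2-fold from their probe's mean. The 8 spike-in controls above background differed by -0.08 to 0.04. In 5800 genes with several measured probes, the 2 brightest differed by a median of 0.11, and of 155 genes at least 2-fold different that had a second probe, it had the same sign in 149 and was also at least 2-fold in 106.

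The 23 gene lists, the rules and most alternatives were fixed before the data were examined. The lists hold 421 distinct genes, of which 6 had no probe under their symbol (Fgf4, Prdm14, L1td1, Hspa1b, Dusp5 and Gapdh). Genes were named by a fixed rule. It took the 12 largest measured differences in each direction among genes with a symbol whose probes share a sign, the 4 largest bounds in each direction, up to 4 genes at least 2-fold different from each list, and 13 genes chosen in advance (Pax6, the reprogramming factors, cadherins and regulators of the transition). A gene that this rule takes from the lists is not reported here. Further list members are named as examples and were chosen after their values were seen.

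Alternatives were scaling by the median, quantile normalization, cyclic loess, normexp background correction (offset 50) with quantile normalization, the deposited series table, the mean or median of a gene's probes, a filter on both arrays or none, a rule of at least 3-fold, a rule that also asked for more than 2 times the measurement error, and unmatched random lists. Scaling to the spike-ins and dim values as measured were added after seeing the data. The steps were tested on simulated data for the comparison of Pax6 with EGFP, run on 18178 genes. Of 200 genes changed by known amounts, 192 were called (88.0% at a log2 change of -1.5, 96.0% at -2.0, and 100.0% at 1.5 and at 2.0), and 0 of 17978 unchanged genes were. The second simulated array was the EGFP array itself with added noise smaller than the measurement error. The 0 calls among unchanged genes therefore say nothing about differences between cultures. Of 200 lists with no shift, 6 fell outside the central 95% of random lists. In further lists all genes were shifted by the same amount, and 50 of 50 were found. That shift was larger in size than the median of any fixed list except the epithelial one. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for quantile normalization, loess and normexp, were used.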

Results

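Gene expression was measured in 2 lines of neural progenitor cells, with 1 array per line. Both lines came from N31, a mouse neural progenitor line derived from induced pluripotent stem cells, in which doxycycline switches on Oct3/4, Sox2, Klf4 and c-Myc, the factors used to reprogram somatic cells to pluripotency. By the labels, one line stably overexpressed EGFP, a green fluorescent protein, and the other Pax6, a paired-box transcription factor of the developing eye and forebrain. RNA was taken 24 h after doxycycline was added, a time at which a change of cell shape had been seen in the EGFP line and not in the Pax6 line. The comparison addressed whether Pax6 affects the mesenchymal to epithelial transition, an early step of reprogramming in which cells take on epithelial features. Of 43379 non-control spots, 28047 (64.7%) were well above background on the EGFP array and 29163 (67.2%) on the Pax6 array, and no spot was saturated. With 1 array per group there is no replicate check and no p-value, and the errors given below cover measurement on these arrays and not the variation between cultures. The number of arrays limits the precision of every comparison. The measurement error of a gene's log2 difference had a median of 0.20.

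In the comparison of Pax6 with EGFP, 919 of 19251 genes above background on at least 1 array differed by at least 2-fold, which is 4.77% of them. On the Pax6 array 452 genes were higher and 467 were lower. Differences of at least 4-fold were found for 89 genes higher on the Pax6 array and 38 lower there. The arrays were otherwise close, with 86.3% of the 19251 genes within 1.5-fold, where genes seen on 1 array count at their lower bound. The Pearson correlation across probes well above background on both arrays was 0.991, where probes of 1 array pair are not independent replicates. The share of the 2-fold genes that were higher was 49.2%, but 59.3% (538 higher, 370 lower) after scaling by the median of each array and 61.8% (176 higher, 109 lower) after normexp background correction with quantile normalization, so no excess in either direction was read from these counts.

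The 2 Pax6 probes measured on both arrays differed by less than 2-fold. The brightest probe, at chromosome 2, 105547907 to 105547966 (mm7), read a signal of 557 on the EGFP array and 822 on the Pax6 array, a log2 difference of 0.35 ± 0.20 (measurement error), or 1.27-fold. The other, within chromosome 2, 105546221 to 105547093, differed by 0.26, with an SD of 0.05 over 9 replicate spots. The remaining Pax6 probe was not well above background on the EGFP array. It was at least 1.23-fold higher on the Pax6 array, a bound that sets no upper limit, and its difference as measured was 2.34 ± 1.46. Whether these probes lie in the part of Pax6 that the transgene carries is not given in the sources used here, so their values check neither the overexpression nor the labels of the arrays, on which every direction given here depends.

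Among the reprogramming factors, Sox2 and Klf4 were higher on the Pax6 array. Sox2 (chromosome 3, 34459231 to 34459290) was 3.34-fold higher, with a log2 difference of 1.74 ± 0.21 and signals of 79.2 and 307. Klf4 (chromosome 4, 55541780 to 55541839) was 2.15-fold higher, with a difference of 1.10 ± 0.20. Pou5f1, the gene of Oct3/4 (chromosome 17, 33612047 to 33612107), was barely detected. Its signal of 7.99 was not well above background on the EGFP array and its signal of 14.3 on the Pax6 array gave a bound of at least 1.19-fold. The probes of Myc disagreed, with log2 differences of -0.02 for the brightest, 0.10 for the next and 1.02 for a probe whose 10 spots had an SD of 0.40. Whether each probe reads the endogenous transcript, the doxycycline-driven one or both is not given in the sources used here. Pou5f1 gave little signal on either array, although doxycycline should switch on Oct3/4 in both lines. Either its probe does not read that transcript or the transcript was scarce, which these arrays cannot tell apart.

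Epithelial genes were lower on the Pax6 array than on the EGFP array. Of the 28 measured members of the epithelial list, 14 were at least 2-fold lower, 0 were at least 2-fold higher and 14 met neither rule. Of the latter, 2 are lower bounds that set no upper limit, Prss8 (at least 1.94-fold lower) and Cdh3 (at least 1.32-fold lower). Cdh1, the gene of E-cadherin, the main adhesion molecule of epithelial cells, was 10.6-fold lower, with signals of 594 and 65.3 (chromosome 8, 105268557 to 105268616). Its log2 difference was -3.40 ± 0.21, and its 8 replicate spots had an SD of 0.097. Lsr, a component of tricellular junctions, was 4.45-fold lower, and Epcam, an epithelial surface adhesion molecule (within chromosome 17, 85952074 to 85952902), was 3.90-fold lower at -1.96 ± 0.21.

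The other epithelial genes at least 2-fold lower included 4 keratins of simple epithelia. These were Krt19 (3.17-fold), Krt8 (2.90-fold), Krt18 (2.66-fold) and Krt7 (2.39-fold). Krt8 and Krt18 have many processed pseudogenes, so their probes can read related sequence. The tight junction genes Cldn3 (2.96-fold), Cldn6 (2.60-fold) and Marveld2 (2.41-fold) were lower as well, as were the epithelial splicing regulator Esrp2 (2.66-fold), the sorting adaptor Ap1m2 (2.44-fold), the junction protein gene Jup (2.21-fold) and the protease inhibitor Spint1 (2.18-fold). Not all epithelial genes were lower. St14 and Dsg2 had log2 differences of 0.74 and 0.67, Dsp differed by -0.03, and Cldn4, Ocln, Crb3 and Esrp1 were not well above background on either array. The median log2 difference of the list was -1.04 (95% bootstrap interval over genes -1.33 to -0.32), and none of 10000 random lists of the same size and similar expression had a median as low (95% of them lay between -0.17 and 0.10). With normexp background correction the median was -0.35 with 9 genes at least 2-fold lower, and Cdh1 and Epcam differed by -2.53 and -1.30.

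**Figure D1:**
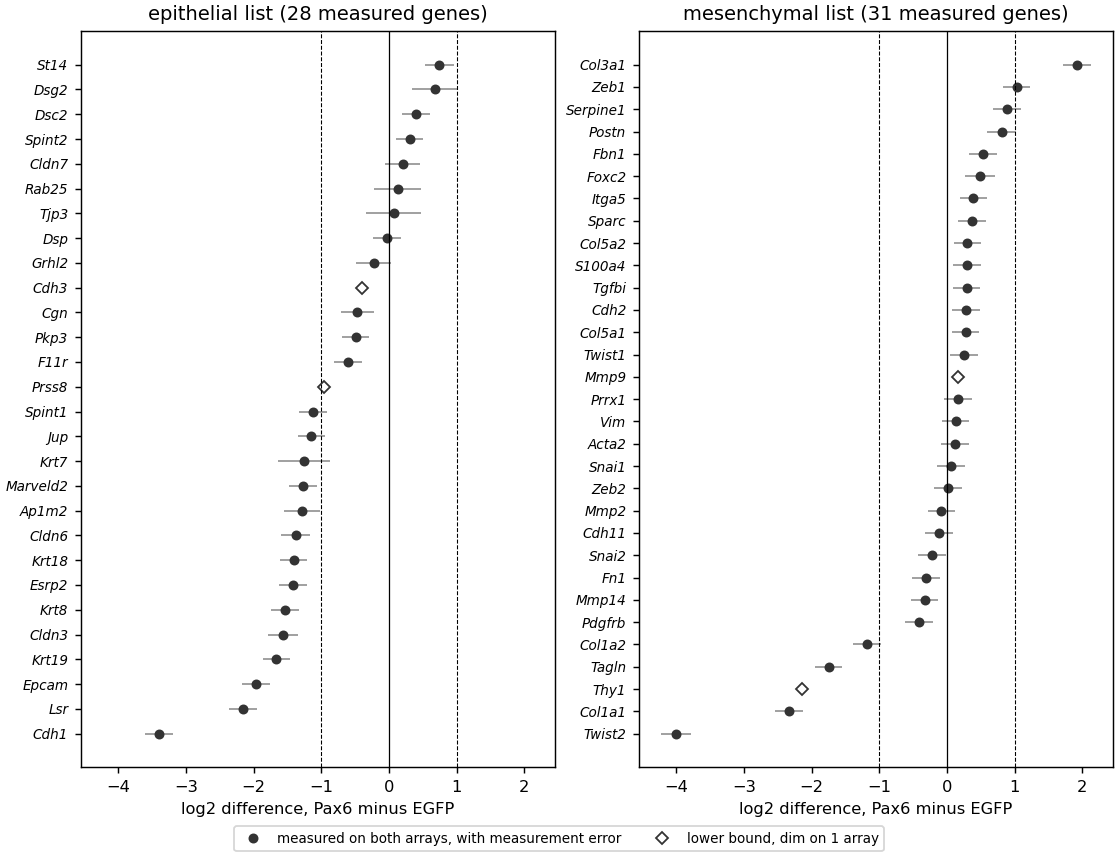
Each point is the log2 difference of a gene, Pax6 minus EGFP, for the 28 measured epithelial and the 31 measured mesenchymal genes, with bars for the measurement error and open diamonds for lower bounds. Dashed lines mark 2-fold, and 14 epithelial genes lie below -1 with Cdh1 lowest at -3.40, while mesenchymal genes spread from Twist2 at -4.01 to Col3a1 at 1.93.

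Most mesenchymal genes lay within 2-fold, but the list differed more than nearly all matched random lists, in both directions. Of 31 measured members, 2 were at least 2-fold higher on the Pax6 array, 5 were at least 2-fold lower and 24 were within 2-fold. The share of all genes at least 2-fold different was 4.77%. The median absolute difference of the list was 0.31, at percentile 99.96 of matched random lists. Among the 24, Mmp9 counts at its lower bound (at least 1.12-fold higher), which sets no upper limit. Of the transcription factors that repress epithelial genes, Zeb1 was 2.04-fold higher (1.03 ± 0.20), and Zeb2, Snai1, Snai2 and Twist1 differed by 0.01, 0.06, -0.22 and 0.26. Twist2, a related factor, was 16.1-fold lower, the largest difference among the lower genes measured on both arrays and named here (-4.01 ± 0.23). Cdh2, the gene of N-cadherin, differed by 0.28 ± 0.20. Of the 5 collagen genes in the list, Col3a1 was 3.80-fold higher, Col1a1 5.03-fold lower and Col1a2 2.27-fold lower, and Col5a1 and Col5a2 differed by 0.28 and 0.30. The actin-binding gene Tagln was 3.36-fold lower and the surface glycoprotein gene Thy1 at least 4.40-fold lower, although Thy1 differed by -0.34 with normexp background correction. The median of the list was 0.16 (interval -0.08 to 0.29), at percentile 99.97 of matched random lists, while its mean was -0.13, so median and mean differed in sign. Among the fibroblast markers, of which 4 are also in the mesenchymal list, Fap was at least 19.2-fold higher and Dcn, the gene of decorin, 7.71-fold higher, while Thy1 was lower. With normexp background correction Fap differed by 1.92 and Col1a1 by -1.70. The median of the 11 measured fibroblast markers was 0.16, at percentile 97.0, and this percentile ranged from 80.74 to 98.15 over the alternatives.

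Feedback genes of FGF and ERK signalling were higher on the Pax6 array by less than 2-fold. Of 14 measured genes, 13 were above 0, with a median of 0.43 (interval 0.19 to 0.46) that lay above those of all 10000 matched random lists. Examples are Egr1, an immediate early gene (0.82 ± 0.20), Spry1, an inhibitor of receptor tyrosine kinase signalling (0.67 ± 0.20), and Dusp6, an ERK phosphatase (0.46 ± 0.20). Ier3 was the exception at -0.63. Genes of glycolysis had a median of 0.14 at percentile 99.44, with 0 of 14 genes different by 2-fold, and this percentile was 95.25 after quantile normalization.

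Among the gene lists of signalling pathways, TGF-beta genes had a median of 0.05 (percentile 86.19). Of 20 genes 1 was counted as 2-fold different, Ltbp2, of the latent TGF-beta binding protein family (2.04-fold lower), with Tgfbr3 at its lower bound (at least 1.02-fold higher). BMP genes had a median of -0.07 (percentile 23.68). The BMP receptor gene Bmpr1b was 2.89-fold higher and the ligand gene Bmp4 2.07-fold higher, while Fst, the gene of the activin antagonist follistatin, was 2.53-fold lower and Id2, a BMP-responsive gene, 2.48-fold lower. Notch genes had a median of -0.12 (percentile 27.24), with Mfng 3.01-fold lower, the ligand gene Jag2 2.45-fold lower and the Notch target Hey1 2.40-fold higher. The median absolute difference of the Notch list was 0.59, at percentile 99.77 of matched random lists, so its genes differed without a shared direction. The 7 measured Wnt targets had a median of 0.10 (percentile 85.12) and none was counted as 2-fold different. Of these, Dkk1 counts at its lower bound (at least 1.07-fold higher), which sets no upper limit. With normexp background correction the differences were within 2-fold for Ltbp2 (-0.22), Bmpr1b (0.60), Bmp4 (0.53), Fst (-0.93), Mfng (-0.98) and Jag2 (-0.73), and Ltbp2 was also within 2-fold under every other scaling tried, between -0.99 and -0.93.

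Pluripotency genes did not stand apart by their median difference 24 h after doxycycline, but this depended on the filter and on the measure. The 22 measured members had a median of -0.10 (interval -0.46 to 0.09) at percentile 23.6. Zfp42, a marker of pluripotent cells also called Rex1, was 2.81-fold lower on the Pax6 array (-1.49 ± 0.21, and -0.81 with normexp background correction). Nanog differed by -0.81 ± 0.31. The percentile was 2.23 when genes had to be above background on both arrays and 0.86 without a filter on dim probes. The median absolute difference of the list was 0.46, at percentile 98.98 of matched random lists.

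Neural progenitor genes also had a median close to 0, -0.03 at percentile 46.83, but held some large differences. Slc1a3, a glutamate transporter gene of radial glia and astrocytes, was 12.9-fold lower on the Pax6 array (-3.69 ± 0.23). Nes, the gene of the progenitor filament nestin, was 3.17-fold lower, and Egfr was 2.40-fold higher. Of 26 genes linked to Pax6 in eye and forebrain, 16 were well above background on at least 1 array, 3 of them as lower bounds. Of these 16, 0 were counted as 2-fold different, and their median was -0.01 (interval -0.15 to 0.18, percentile 58.73). The share over all genes was 4.77%, so a count of 0 among so few genes says little. Without a filter on dim probes, 3 of the 26 were at least 2-fold higher and 1 at least 2-fold lower.

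Markers of other neural cell types differed in direction. Oligodendrocyte lineage genes had a median of -0.45 (interval -0.63 to 0.06, percentile 0.13), with 6 of 8 below 0. Of these, the myelin gene Mbp was 2.10-fold lower, while Pdgfra, a receptor gene of oligodendrocyte precursors and mesenchymal cells, was 3.78-fold higher. Astrocyte markers had a median of 0.37 (interval 0.01 to 0.66, percentile 99.81), with 7 of 8 above 0 and the water channel gene Aqp4 at least 3.86-fold higher, although Slc1a3, which astrocytes also express, was lower. Neuronal genes had a median of -0.33 (interval -0.48 to 0.06, percentile 0.76), and the synaptic vesicle fusion gene Snap25 was 3.15-fold lower. The intervals of the oligodendrocyte and neuronal lists include 0. Aqp4 and Pdgfra differed by 0.50 and 1.13 with normexp background correction, and Mbp by -0.90 and -0.84 with the mean and median of a gene's probes and by -0.99 after scaling by the median. The neuronal percentile was 21.97 with normexp background correction, 17.75 without a filter on dim probes, and 4.62 and 4.46 with the mean and median of a gene's probes.

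Markers of unrelated cell types gave no list outside the range of matched random lists. The endothelial list had a median of -0.18 (percentile 19.9, 6 measured genes), the microglia and blood list 0.04 (percentile 72.0, 5 genes) and the mesendoderm list 0.10 (percentile 81.2, 6 genes), in which the chemokine receptor gene Cxcr4 was 3.43-fold higher. Medians were 0.07 for 26 cell cycle genes (percentile 93.2), -0.02 for p53 and senescence genes (34.02), -0.23 for interferon genes (4.61), 0.08 for cell stress genes (91.34) and 0.04 for housekeeping genes (69.95). In these lists Eda2r, a p53 target, was 4.48-fold higher, Usp18, an interferon-induced protease gene, 3.65-fold lower and Vldlr 2.21-fold higher. With normexp background correction Eda2r differed by 1.11, and Cxcr4, Usp18 and Vldlr differed by 0.98, -0.73 and 0.95, within 2-fold. About 5.0% of random lists fall outside the central 95% by construction, and 7 of the 23 lists did here. Random lists draw genes independently, whereas genes of a real list can vary together and some lists share genes. These shares therefore do not measure an excess.

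**Figure D2:**
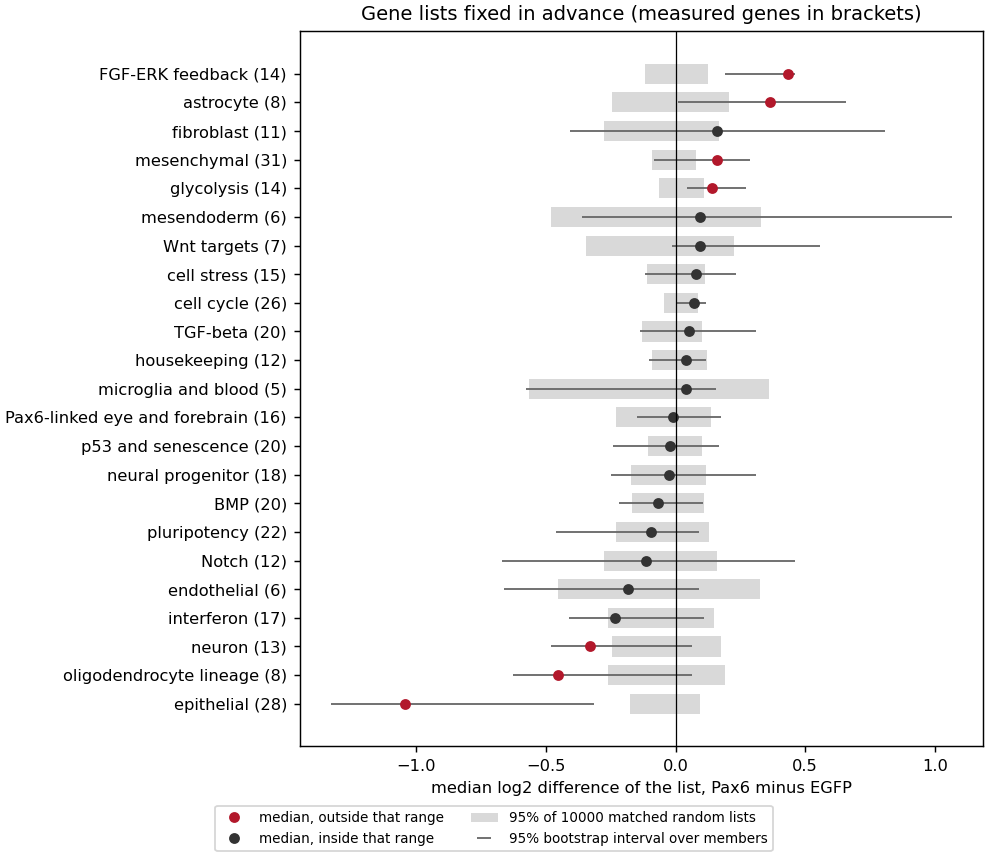
Points are the median log2 differences, Pax6 minus EGFP, of the 23 gene lists, lines are 95% bootstrap intervals over their measured genes and grey bars hold 95% of 10000 random lists matched on expression. The epithelial list lies lowest at -1.04 and the FGF and ERK feedback list highest at 0.43.

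Among the genes named here, the largest differences were those of genes higher on the Pax6 array. Crym, a thyroid hormone binding protein gene (chromosome 7, 116108739 to 116108798), was 33.2-fold higher, with a log2 difference of 5.05 ± 0.21 and signals of 52.0 and 1999. Fbln5, an elastic fibre gene (chromosome 12, 99245331 to 99245390), was 27.7-fold higher (4.79 ± 0.31), and the chemokine gene Cxcl14 (chromosome 13, 55377968 to 55378027) 16.3-fold higher (4.03 ± 0.21). The ectoenzyme genes Entpd1 and Enpp1 were 12.7-fold and 11.8-fold higher. Masp1, of the lectin complement pathway, was 10.5-fold higher, Nckap1l, an actin regulator of blood cells, 10.4-fold, Lrrc17 9.60-fold, the integrin gene Itga1 9.20-fold, Pgm5 8.74-fold, the endocytosis gene Amph 8.37-fold and Mydgf 8.28-fold. S100a8, a calcium-binding protein gene of myeloid cells, was well above background on the Pax6 array only and at least 36.9-fold higher. The same held for Spats2l (at least 30.4-fold) and Icam2, an adhesion molecule gene of endothelial and blood cells (at least 18.6-fold).

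The next ranking on the lower side covers genes measured on both arrays that have a symbol and whose probes share a sign. After Twist2, Slc1a3 and Cdh1, the largest differences among them were those of Mapk13, a p38 kinase gene (7.78-fold lower, -2.96 ± 0.20), Slc5a7, the choline transporter gene of cholinergic neurons (7.16-fold), and Stra8, a retinoic acid induced gene of germ cells (6.55-fold). Serpinb10, Fam20c, Mmp28, Tmem163, Xlr5c and Plce1 were 6.22, 6.06, 6.04, 5.86, 5.57 and 5.55-fold lower. Xlr5c belongs to a family of near-identical genes on the X chromosome, so its probe can read several of them. Well above background on the EGFP array only were Ano9 (at least 8.11-fold lower on the Pax6 array), Baiap2l1 (at least 6.20-fold), Ralyl (at least 4.92-fold) and Sh3gl2 (at least 4.91-fold). Normexp background correction, which draws dim probes towards 0, lowered many of these sizes, to 4.04 for the log2 difference of Crym, 2.67 for Fbln5, 2.91 for S100a8, 2.43 for Spats2l, 1.86 for Icam2, -2.40 for Twist2, -2.18 for Slc1a3 and -1.49 for Stra8. Lrrc17, Pgm5, Nckap1l, Masp1 and Amph differed by 1.81, 1.83, 2.42, 2.67 and 2.42, and Serpinb10, Fam20c, Mmp28, Xlr5c and Plce1 by -1.30, -1.23, -1.73, -1.64 and -1.03. It left Ano9 (-0.92), Baiap2l1 (-0.69), Ralyl (-0.61), Sh3gl2 (-0.62) and Tmem163 (-0.86) within 2-fold. Averaging all probes of a gene gave -2.74 for Slc1a3, 1.60 for Amph, 1.87 for Masp1 and 3.30 for Spats2l, whose probes disagreed in size.

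**Figure D3:**
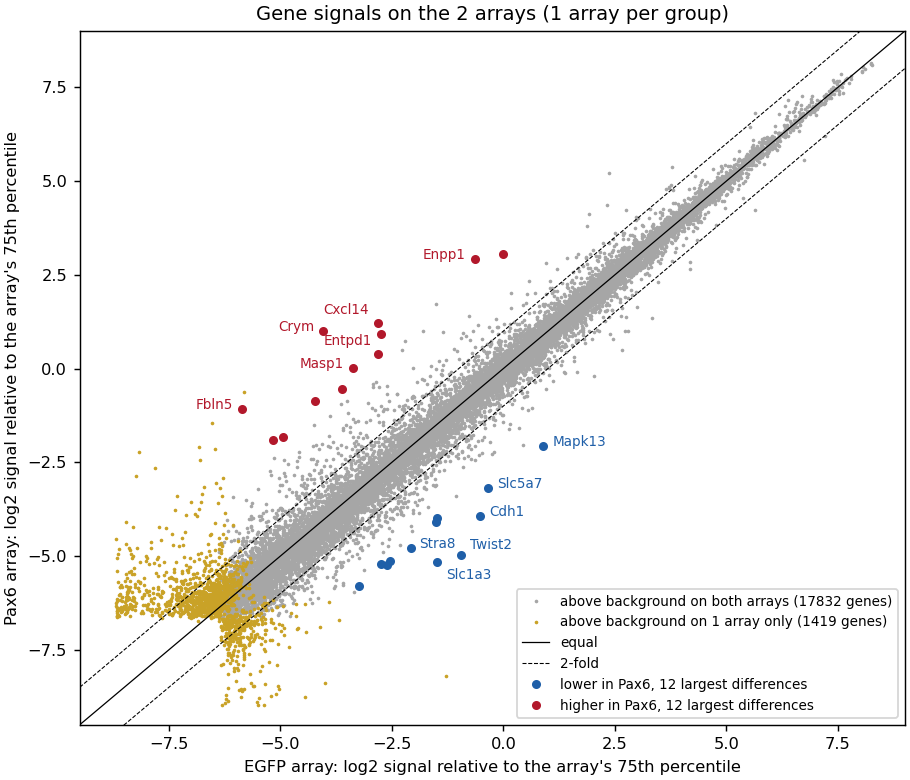
Each point is a gene, with its log2 signal relative to the array's 75th percentile on the EGFP array (x axis) and on the Pax6 array (y axis). Dashed lines mark 2-fold, coloured circles mark the 12 largest measured differences in each direction among genes with a symbol, and of these circles Crym lies farthest from the line of equal signal with a difference of 5.05.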

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

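The alternatives with spike-in scaling and with dim values as measured were chosen only after the results were seen. Of 62 genes at least 2-fold different that the naming rule took, 0 changed sign under any alternative, and no list outside the central 95% of random lists did. With normexp 18 of the 62 fell within 2-fold. Of 1011 alternative values of gene differences and list medians, 926 stayed within the measurement error (genes) or the bootstrap interval over genes (medians). Many of them could hardly move by construction. The deposited series table holds the same values, and changes of the filter on dim probes largely leave genes measured on both arrays as they were. This count is therefore no measure of robustness. The epithelial median stayed at percentile 0.0 throughout, between -1.14 and -0.35. The deposited series table moved nothing, since it holds the same values. No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate.

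Counts of 2-fold genes (452 higher, 467 lower) were 176 and 109 (285 in all) with normexp, which kept 282 of the original calls, 1307 and 1232 (2539) with no filter on dim probes, and 713 higher with dim values as measured. A 3-fold rule gave 165 and 103 (268), fewer by construction. Normexp gave -2.53 for Cdh1, -1.30 for Epcam and 1.24 for Sox2. It put the neuron list at percentile 21.97, fibroblast at 97.5 and cell stress at 98.39, the last 2 newly at or beyond the limit of 97.5. Scaling by the median added 0.082 to differences measured on both arrays, and the medians were 0.151 for cell cycle, 0.515 for FGF and ERK feedback and 0.124 for housekeeping genes. Spike-in scaling gave 0.471 for FGF and ERK feedback. Quantile normalization put glycolysis at 95.25. The mean of a gene's probes gave 0.367 for Myc and percentiles of 4.62 for neuron and 98.15 for fibroblast; the median of probes gave 0.077 for Cdh2 and 4.46 for neuron. Asking for signal above background on both arrays put pluripotency at 2.23, and no filter put it at 0.86 and neuron at 17.75. Unmatched random lists put interferon at 0.65. Where construction does not show it, the cause was not tested.

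Of 616 alternative values of the other named genes, 76 moved beyond their error, 68 of them nearer to 0, and 47 came from normexp, whose offset of 50 is close to the signal of dim probes. Signal over background limits the 1419 genes seen on 1 array, for which the size is a bound.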

Other observations

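The tests on pluripotent cells, on induction of the factors and on the Pax6 probes were chosen only after the result was seen, and the 4 gene lists below were written after genes in them had been noticed.

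Some genes with vesicle functions were higher on the Pax6 array and others lower, and some muscle-type contractile genes were lower. Cadps, a priming factor of dense-core vesicle release, was 6.93-fold higher, the clathrin assembly gene Snap91 4.45-fold and Rimbp2, of the presynaptic active zone, 4.13-fold, beside Amph, while Snap25 was 3.15-fold lower and the endocytosis gene Sh3gl2 at least 4.91-fold lower. Fhl1 was 4.68-fold lower, the calponin gene Cnn1 4.05-fold and the desmin gene Des 2.90-fold, beside Tagln. The medians of lists of related genes lay within the range of matched random lists. Of 21 further measured genes of vesicle exocytosis, 1 was at least 2-fold higher (Syn1, 3.44-fold) and 1 at least 2-fold lower (Cplx1, 2.05-fold), with a median of -0.04 at percentile 37.18 of matched random lists. Of 16 further smooth muscle contractile genes, 0 differed by 2-fold, with a median of 0.06 at percentile 85.77. By median absolute difference the vesicle list lay at percentile 54.42 and the smooth muscle list at 88.19. The share over all genes was 4.77%, so 2-fold counts among so few genes say little.

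The lower level of epithelial genes on the Pax6 array was set against 1 technical and 2 other explanations. Uneven hybridization is argued against by the spots around the 14 epithelial probes at least 2-fold lower (21 spots, each with the neighbours within 10 rows and 5 columns), whose median difference was -0.018 and ranged from -0.093 to 0.044. Fully reprogrammed cells on the EGFP array were also tested as the cause of the whole pattern. Of 6 transcripts of pluripotent cells detected there, 5 lay above the epithelial median by more than 2 measurement errors (Dppa5a, Dppa2, Utf1, Tdgf1 and Tdh, from -0.14 to 0.22). Of these, Tdgf1, Tdh and Utf1 were dim there (signals of 12.38, 25.35 and 35.53, against a lowest signal well above background of 10.4), so they exclude little. Dppa4 and Lin28a were not well above background on either array. Esrrb and Pou5f1 were well above background on the Pax6 array only, where they were dim (signals of 17.37 and 14.3). Transcripts undetected on the EGFP array could not enter this test, and whether their probes read them was not checked. Zfp42 was lower at -1.49. Of the 22 measured pluripotency genes, 15 were below 0, among them Nanog (-0.81) and Dnmt3l (-0.90), and 7 were above. The values of Dppa5a and Dppa2 argue against such cells for these transcripts only. The explanation is not settled, and a small share of such cells is not excluded. Weaker induction of the reprogramming factors might also lower these genes. The brightest probes of the 4 factors had a median difference of 0.676 towards the Pax6 array, with Pou5f1 at its lower bound. It is unknown whether these probes read the transgenes, so this median decides nothing. An effect of Pax6 on the transition, which the design asks about, stays open as well, since 1 array per line cannot separate it from other differences between the lines.

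The small difference of the Pax6 probes measured on both arrays (1.27-fold for the brightest) may come from probes that lie outside the transgene's transcript. With the dimmest probe counted at its lower bound, the largest difference of a Pax6 probe was that of the brightest (an excess of 0.0). This decides nothing, since the bound sets no upper limit, the dimmest probe differed by 2.34 ± 1.46 as measured, and where the probes lie relative to the transgene is unknown. This explanation therefore cannot be told apart from a low level of overexpression.

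Igf2r was 4.33-fold higher and Dlk1 3.98-fold lower on the Pax6 array, and both are imprinted genes, expressed mainly from the copy of 1 parent. The hypothesis that imprinted expression had diverged between the lines was tested on 18 other measured imprinted genes. Their median absolute difference was 0.41, at percentile 99.63 of matched random lists, with Phlda2 2.34-fold and Igf2 2.11-fold lower. This is in line with the hypothesis but not specific to it, since 7 of the 23 lists fixed in advance also lay above percentile 97.5 by absolute difference. Expression from the parental copies was not measured.

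Some retinoic acid responsive genes were lower on the Pax6 array, among them Stra8 (6.55-fold), Rarb, a retinoic acid receptor gene (3.88-fold) and Hoxb2 (2.42-fold). The hypothesis of a lower retinoic acid response in the Pax6 line was tested on 15 other measured genes, whose median was 0.01 (interval -0.69 to 0.89) at percentile 69.3. They went both ways, with Dhrs3 at least 3.89-fold lower, Hoxb3 2.72-fold higher and Cyp26b1, the gene of a retinoic acid degrading enzyme, 2.08-fold higher. The median absolute difference of these 15 genes was 0.69, above the 0.34 that marks percentile 97.5 of matched random lists. The genes therefore differed more than most such lists, without a shared direction. This is not specific to them, since 7 of the 23 lists fixed in advance also lay above percentile 97.5 by absolute difference. The test gave no sign of a shared decrease, and members moving in both directions leave the question open.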
